A study of Mus musculus with 8 samples.

How the data were processed

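Cells of the mouse cervix were profiled by single-cell RNA sequencing in 8 libraries, 1 per group. Per the labels' protocols, cervices were dissected below the transition zone, vaginal tissue was removed, and cells were freed with a protease in the cold before 10x v3 libraries were made. The groups were wild type non-pregnant, GD6, GD12, GD15, GD18 and in labor, and the labelled hyaluronan synthase knockout at GD15 and GD18. Groups were taken from the labels. The labels do not record sequencing or library dates, so library batches cannot be told from groups. They also do not say how the animals of a group were pooled.

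The deposited matrices hold UMI counts per gene and barcode, as whole numbers and not normalized. Per the submitters' processing notes they were made with Cell Ranger 3.0.2 on the mm10 build. They list 31053 gene IDs with symbols, of which 30934 matched GENCODE vM21 (GRCm38) for positions. Every barcode held at least 500 UMIs in the deposited matrices. Depth per library was 56423277 UMIs for non-pregnant, 38603328 for GD6, 50400029 for GD12, 35881825 for GD15, 58769695 for GD18, 57467725 for in labor, and 104816758 and 95755740 for the labelled knockout at GD15 and GD18.

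Barcodes with at least 500 genes and at most 20% mitochondrial counts were kept. These were 62.4% of barcodes in the non-pregnant and GD6 libraries, 69.9% at GD12, 48.9% at GD15, 68.6% at GD18, 64.3% in labor and 80.3% and 79.0% in the labelled knockout. Doublets were called with Scrublet in scanpy 1.11.5 per library. It marked 138 cells at GD6, between 1 and 4 in each other wild type library, and 0 in the labelled knockout libraries. That is far under the number such loads give, so the calls did not work as a filter, and an alternative with an expected rate was added after this had been seen.

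Counts were scaled to 10000 per cell and log transformed. Genes that vary within libraries were chosen (3000, of which 2989 were used after mitochondrial, ribosomal, hemoglobin and Xist genes were left out). All libraries were clustered jointly from 30 principal components and 15 neighbours with the Leiden method (igraph 0.11.9) at resolution 1. No batch correction was used, since each group is a library of its own. Clusters were named from marker lists written before the data were examined. A non-epithelial name needed a mean log2 fold of its markers of at least 1, at least 3 markers at that fold, and Krt5 in under 70% of cells. An epithelial name needed Krt5 in at least 70% or Epcam in at least 90% of cells, with its leading genes not those of another class. Other clusters were left unnamed. These naming thresholds were set after the clusters had been seen. Clusters of low UMI counts without a marker among their 10 leading genes were left unnamed too. Epithelial clusters were placed in basal, suprabasal squamous, and secretory or columnar subclasses by the same markers where these scored high enough, and the others were left in no subclass. Those in no subclass were 46.1% and 48.2% of wild type epithelial cells at GD15 and GD18, and 58.3% and 56.1% of labelled knockout ones.

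For each class and library, UMIs were summed and expressed as CPM of the sum. Folds are log2 ratios of CPM, with a floor of 3 counts. The 95% intervals are exact: Poisson for summed counts, and Clopper-Pearson for shares and for the ratio of 2 counts. They cover counting error only, not differences between animals. UMIs of the same cell are taken as independent, so the intervals of summed counts and folds do not cover the sampling of cells either. With 1 library per group no test was run and no p-value is given. Values of Has1, Has2 and Has3 were read first as a check of the labels.

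Before the data were examined, 26 gene lists and the rule for naming genes were fixed. A list member was measured at a CPM of at least 5 in either library. It was called higher or lower at a fold of at least 1.5 with an interval excluding no change. The median log2 fold of a list was placed among 10000 random lists matched on expression in 20 bins, which describes these libraries and tests nothing about animals. Genes named had a CPM of at least 20 in the higher library and there at least 50% of the CPM of every other class with 100 cells. Mitochondrial, ribosomal, hemoglobin, Xist and unnamed genes were left out. The rule took the 12 highest and 12 lowest genes by the smallest fold over the pregnant libraries against non-pregnant, over GD18 and in labor against GD15, and over both days of the labelled knockout. It took 3 each way for each step between stages and 5 each way for the difference of folds between days and for each other class. List members and Has genes could be named too. A gene that the rule names is not reported here. Which list members to print, and which results to treat as main ones, was chosen after values had been seen. Some genes with near-identical relatives are marked as uncertain where named, which was judged from gene families and not from an alignment.

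The fold, interval and list steps were tested on simulated data. For labelled knockout against wild type at GD15, counts were drawn for 9458 genes with 200 of them changed. Of 50 genes changed by a fold of 2, 50 were called, and 0 of 9258 unchanged genes were called. The intervals held the true fold for 95.6% of genes. Of 100 random lists of unchanged genes, 4 fell outside the 2.5th to 97.5th percentile. The simulation has counting error alone.

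Alternatives fixed before the data were examined were other cell filters (200 genes, or 1000 genes with 10% mitochondrial counts), doublets kept, Leiden resolutions of 0.5 and 2, totals without the 50 most abundant genes, TMM scaling with edgeR 4.0.16, the mean of per-cell CPM, thinning to 2000 UMIs per cell, subtraction of free RNA (the profile of all cells of a library, at a share estimated from fibroblast and immune markers in epithelial cells), equal weight to the epithelial subclasses, other CPM minimums and a fold of at least 2. A further 3 kinds were added later, namely removal of the highest doublet scores at 0.8% per 1000 barcodes, counting unnamed Krt5-rich clusters as epithelial, and leaving out cluster 32. Sizes of epithelial subclasses were not compared. Gene sets beyond the fixed lists, trajectories and other cell classes under 100 cells were not analysed here.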

Results

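Single-cell RNA sequencing (10x v3 chemistry, which tags the 3′ end of each transcript) was carried out on cells of the mouse cervix. Each group had 1 library. The wild type groups were non-pregnant, gestation day (GD) 6, GD12, GD15, GD18 and in labor. The other libraries came from GD15 and GD18 animals labelled as lacking hyaluronan synthases. The genotype label names Has1 and Has3 as deleted and Has2 as deleted by a Cre under the progesterone receptor gene. Per the series' design, the wild type groups drew on 7 diestrus and 2 estrus animals when non-pregnant, then 5, 4, 3, 3 and 3 animals in the order of pregnancy. There were no replicate libraries, so no difference could be set against a spread between animals. The intervals given are 95% intervals for counting error.

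The 8 libraries held 72684 barcodes and 498118377 unique molecular identifiers (UMIs). Totals per library ran from 35881825 UMIs at GD15 to 104816758 UMIs in the labelled knockout at GD15. After filtering, 50997 cells were kept, from 2332 at GD15 to 13282 in the labelled knockout at GD15. The median depth of kept cells ran from 4833.5 UMIs at GD6 to 14080.5 UMIs in labor.

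The first comparison asked which cells the cervix released at each stage. Epithelial cells were the most numerous class in every library. GD6 had the lowest epithelial share and the highest shares of neutrophil-like, macrophage-like and endothelial cells. The ranks of the epithelial and neutrophil-like shares depended on the setting. With at least 1000 genes per cell GD12 (56.7%) and GD15 (57.7%) were lower than GD6 (65.8%). With doublet scores removed at an expected rate, in labor (50.04%) was lower than GD6 (52.5%). In each setting the rule left a cluster with Krt5 in 100% of its cells unnamed. At 1000 genes it had 3141 cells, of which 37.6% were from GD12, 18.7% from GD15 and 2.58% from GD6. With doublet scores removed it had 1713 cells, of which 41.2% were from in labor and none from GD6. The changed epithelial ranks thus rest on naming as well as on filtering. With at least 200 genes per cell the neutrophil-like share was higher in the non-pregnant library than at GD6. The neutrophil-like cluster then had 3369 cells, of which 34.1% were non-pregnant and 37.3% from GD6. Before doublet calls, 5576 non-pregnant and 8406 GD6 barcodes passed that filter. Shares depend on what the protease set free as well as on the tissue.

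Epithelial cells made up 83.1% of the kept cells in the non-pregnant library (exact binomial interval 82.0% to 84.3%). The epithelial share was 41.9% at GD6 (40.6% to 43.2%), 59.2% at GD12, 72.6% at GD15, 88.0% at GD18 and 70.4% in labor. It was 85.8% and 87.8% in the labelled knockout at GD15 and GD18. Neutrophil-like cells made up 4.18% of the non-pregnant library, 14.2% at GD6, 10.9% at GD12 and 1.16% at GD15. Endothelial cells made up 13.3% at GD6 (772 cells), 5.11% at GD12 and 0.338% in the non-pregnant library. Macrophage-like cells made up 10.1% at GD6 and 3.77% at GD12. Cells of clusters that met no naming rule made up 6.83% of the non-pregnant library, 13.2% at GD6, 19.6% at GD12, 20.5% at GD15, 10.1% at GD18 and 22.8% in labor. In the labelled knockout they made up 13.0% and 11.2%. Cluster 14, led by Siglech and Irf8, was named dendritic-like by the rule and held 158 cells at GD6 against 18 in the non-pregnant library. With the filter of 200 genes per cell the cluster with these genes was named B-like.

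**Figure D1:**
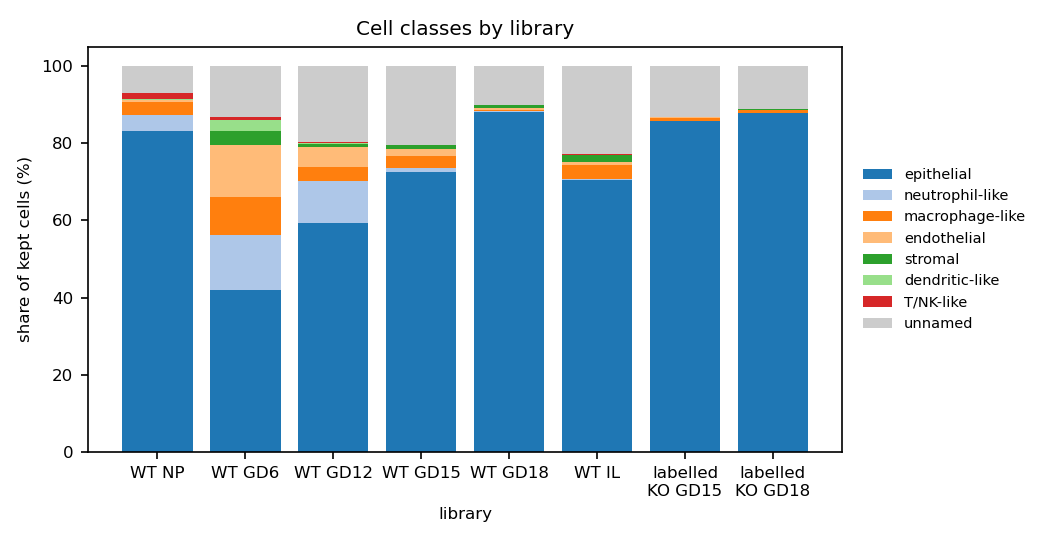
Share of kept cells (%) by class in each of the 8 libraries; each bar is 1 library and the grey part is cells left unnamed. GD6 has the lowest epithelial share, 41.9%, with the cell filter and doublet calls used here, and not with each alternative.

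The targeted genes were looked at next, as a check of the labels. The 3′ tags of Has2 (ENSMUSG00000022367, chromosome 15, 56665627 to 56694539, GRCm38) were not lower in the labelled knockout epithelium. Has1 tags were more numerous there than in any wild type epithelium. A tag outside the deleted part of a gene checks nothing, and the labels do not give that part.

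Epithelial Has2 stood at 7.25 CPM (counts scaled to the same library total) in wild type and 12.8 CPM in the labelled knockout at GD15. At GD18 it stood at 7.71 and 18.4 CPM. With equal weight to the epithelial subclasses, which leaves out unnamed cells and cells of no subclass, its log2 fold at GD15 was -0.011. In unnamed cells Has2 stood at 1.20 CPM (4 UMIs) in wild type and 27.5 CPM (114 UMIs) in the labelled knockout at GD15. At GD18 it stood there at 3.13 CPM (8 UMIs) and 42.5 CPM (147 UMIs). Unnamed cluster 13, with Krt5 in 94.7% of its cells, had Has2 among its 10 leading genes. Has2 UMIs were seen in 4.91% of wild type and 5.62% of labelled knockout epithelial cells at GD15. Epithelial Has3 (ENSMUSG00000031910, chromosome 8, 106870242 to 106884566) stood at 7.95 against 5.42 CPM at GD15 and at 9.79 against 6.05 CPM at GD18. Epithelial Has1 (ENSMUSG00000003665, chromosome 17, 17843323 to 17855205) had 229 UMIs (2.37 CPM) in the labelled knockout at GD15 and 99 UMIs (1.12 CPM) at GD18, against 3 UMIs and 1 UMI in wild type. Over the wild type stages epithelial Has2 was highest at GD6, at 44.6 CPM, against 10.6 CPM in the non-pregnant library and 21.6 CPM in labor.

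The main question of the series was how the cervical epithelium differs between stages of pregnancy. Epithelium from GD6 to GD18 had far lower cornification transcripts than non-pregnant epithelium, and at GD6 far lower Krt16. The mucus and columnar lists were higher at GD6, and single genes such as Agr2, Krt18 and Cldn10 were higher at each stage from GD6 to GD18. GD6 stood apart by higher interferon transcripts. Antigen presentation transcripts were higher at GD6 and GD12, and tight junction transcripts at GD6 depended on the scaling. In labor, Krt16 and Krt5 were again near the non-pregnant level, but 12 of 20 cornification genes were lower than there (median log2 fold -1.25). The epithelial cells compared were not of the same clusters. Clusters 0 to 4 held 96.9% of non-pregnant and 98.3% of in-labor epithelial cells but 2.39% at GD6. Clusters 15, 17, 19 and 24 held 80.5% at GD6, 65.4% at GD12, 61.2% at GD15 and 45.6% at GD18.

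By the rule, 24 genes were chosen for a difference in the same direction at all 5 pregnant stages. The water channel gene Aqp8 (ENSMUSG00000030762) stood at 1.30 CPM in non-pregnant epithelium and between 26.8 and 92.6 CPM in the pregnant libraries. The claudin gene Cldn10 stood at 14.2 CPM and between 204 and 244 CPM. Aldh3a1, Clca1, Pdzrn4, Krt18, Aqp5, Galnt12, F3, Id4, Sgms2 and Tmem213 were also higher, with smallest log2 folds from 1.64 (Tmem213) to 3.56 (Aldh3a1). The lower genes were led by Spink12, at 206 CPM in non-pregnant epithelium and at most 3.01 CPM in the pregnant libraries. Mt4, Il1f6, Sprr2b, Sprr2e, Dsc1, Sprr1b, Ppbp, Krtdap, Tmem266, Stfa3 and Cspg4 were also lower. Sprr2b, Sprr2e and Stfa3 have near-identical relatives, so their tags are uncertain.

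**Figure D2:**
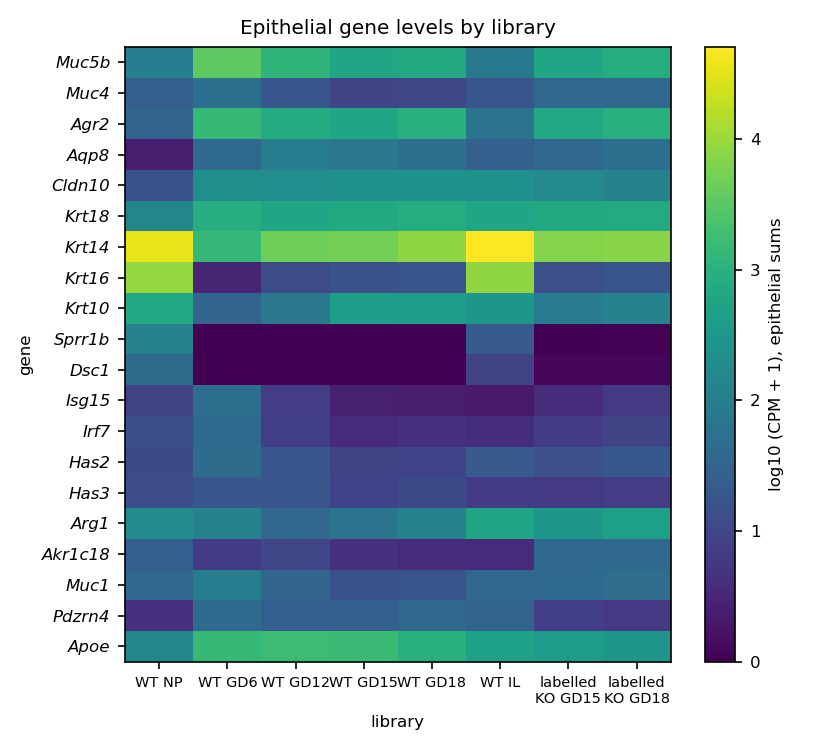
Epithelial level of 20 genes (rows) in the 8 libraries (columns), as log10 of CPM plus 1 of the summed epithelial counts. Krt16 stands at 8958 CPM in the non-pregnant and 8496 CPM in the in-labor library.

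At GD6 against non-pregnant, 18 of 19 measured mucus and secretory genes were higher, with a median log2 fold of 2.27. Random lists of matched expression had a median of 0.27, since the median of all genes was itself 0.32 higher. Muc5b stood at 3487 CPM against 104 CPM (log2 fold 5.07, interval 5.03 to 5.11), and Agr2 had a log2 fold of 5.45. Tff1 was lower. All 20 measured cornification genes were lower at GD6, with a median log2 fold of -5.34. They remained lower at GD12 (20 of 20), GD15 (20 of 20) and GD18 (19 of 20). Krt16 stood at 8958 CPM in non-pregnant epithelium and at 2.09 CPM at GD6. The columnar list had 10 of 13 members higher at GD6 (median 1.86). The desmosome list had 12 of 19 lower (median -1.91) and glycolysis 16 of 21 lower (median -1.80).

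The tight junction list had 16 of 20 members higher at GD6, with a median of 1.17 against 0.45 for random lists. With TMM scaling, which shifts the median of all genes by -0.56 in this comparison, 9 of 19 tight junction members were higher, with a median of 0.50 against 0.56 at GD18 and 0.71 in labor. The interferon list had 18 of 19 members higher (17 with TMM) and a median of 1.82. Isg15 stood at 49.2 CPM at GD6 against 7.30 CPM in the non-pregnant library. The antigen presentation list had 14 of 14 members higher (12 of 13 with TMM), and 12 of 13 at GD12 (10 with TMM). Its class I gene H2-K1 stood at 536 against 167 CPM. Its class II genes H2-Aa, H2-Ab1, H2-Eb1 and Cd74 were also higher, but at GD6 their epithelial levels were not separable from macrophage RNA. Of the steroid list, Pgr was lower at GD6 (64.8 against 187 CPM) and Esr1 higher (232 against 100.3 CPM). The genes with the largest folds at GD6, Prss29, Prss28 and Spink1, lead cluster 32, which held 6.18% of the GD6 epithelial cells and none of the non-pregnant ones. They had no UMI in non-pregnant epithelium, so their log2 folds, set against a floor of 3 counts, were at least 14.51, 13.71 and 12.90. Without this cluster they were at least 8.67, 7.77 and 7.25. Leaving out its cells, here and below, does not take off their free RNA in other cells. Whether the cells of this cluster belong to the cervix was not tested, so these folds may not be those of cervical epithelium. Prss28 and Prss29 are close relatives, so their tags are uncertain.

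From GD6 to GD12, all 19 measured interferon genes were lower (median -1.82), as were 15 of 19 mucus genes and 12 of 19 tight junction genes. With TMM scaling, which shifts the median of all genes by 0.31 here, these were 17 of 17 interferon, 9 of 18 mucus and 5 of 18 tight junction genes. The cell cycle list had 12 of 24 members higher at GD12. At GD15 against GD12, 21 of 24 cell cycle genes were lower (median -0.96), with 11 of 14 antimicrobial, 10 of 13 antigen presentation and 9 of 12 interferon genes. With TMM scaling, which shifts the median of all genes by 0.23 here, 16 cell cycle, 7 antigen presentation and 8 interferon genes were lower. Pigr stood at 28.7 against 160 CPM. S100a8 and S100a9 were lower too, but neutrophil-like cells were 1.16% against 10.9% of those libraries. Krt6b and Krt10 were higher at GD15, with log2 folds of 2.59 and 2.42, though the tags of Krt6b are uncertain beside those of its relative Krt6a. GD18 differed little from GD15, with a correlation across genes of 0.977 (Pearson's r of log2 CPM, 6633 genes, which are not independent replicates). Rbp2 (log2 fold 2.08) and Ecm1 were higher at GD18. Klk1, Napsa and Guca2b, which lead cluster 32, were lower. That cluster held 1.06% of GD15 epithelial cells and none at GD18, and without it the log2 fold of Napsa was -3.69 against -9.53 with it. Klk1 had no UMI and Guca2b 1 UMI at GD18.

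In labor against GD18, 15 of 16 measured cornification genes were higher, with a median log2 fold of 3.48. Krt16 had a log2 fold of 9.01 and Mt4 of 8.65. Dsg1a stood at 91.3 CPM in labor and Krt14 at 50711 CPM in labor. The desmosome list had 14 of 18 members higher (median 1.36), glycolysis 19 of 21 (median 1.46) and cholesterol synthesis 14 of 20 (median 0.85). Slc2a1 stood at 517 against 98.7 CPM. Of 18 mucus genes 6 were higher and 8 lower. Cyp2f2, Fmo2 and St6galnac1 were lower, and Kap was higher. The dissociation stress list had 13 of 20 members higher (median 1.02), which bears on every in-labor value. The in-labor epithelium correlated across genes with the non-pregnant one at 0.925 and with GD18 at 0.884. It was not the same as non-pregnant epithelium, with 12 of 20 cornification genes lower, 12 of 13 interferon genes lower and 10 of 17 mucus genes higher than there.

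Of the genes that were higher or lower than GD15 at both GD18 and in labor, Rbp2, Ecm1, Psca, Sprr2a3, Teddm3, Pmepa1, Ly6k, Tuba4a, Arg1, Slc2a1 and Fam25c were higher. Psca stood at 23.3 CPM at GD15, 71.1 CPM at GD18 and 963 CPM in labor. Abcb1b, Fam13a, Cuzd1, Lbp, Apobec3, Cbx6 and Tpm3-rs7 were lower. Sprr2a3 and Tpm3-rs7 have near-identical relatives, so their tags are uncertain. Guca2b, Sult1d1, Napsa, Klk1 and C3 were lower with and without cluster 32.

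The second question was how the epithelium differs when the animals are labelled as lacking hyaluronan synthases. The labelled knockout epithelium had higher Muc4, Muc1, Arg1 and Akr1c18 than wild type at both days. It had lower Apoe, Apoc1, Krt10 and Pdzrn4. Its log2 folds at GD15 and GD18 correlated across 6622 genes with an r of 0.755 (genes are not independent replicates). Clusters 18, 20, 21, 25 and 26 held 76.0% and 76.6% of the labelled knockout epithelial cells, against 14.2% and 24.7% in wild type. The median of all genes was 0.24 higher at GD15 and 0.27 higher at GD18, and TMM scaling shifts it by -0.22 and -0.28.

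Akr1c18 stood at 3.68 CPM in wild type and 36.7 CPM in the labelled knockout at GD15, and at 3.10 and 37.7 CPM at GD18. Muc4 stood at 8.73 against 34.7 CPM and at 9.29 against 38.6 CPM. Arg1 stood at 62.6 against 307 CPM and at 129 against 444 CPM. Ankrd37, Aoc1, Ifi202b, Mid1, Adam28, Ndrg1, Muc1, Ppp1r9a and Ramp1 were also higher, with smaller log2 folds of the 2 days from 1.43 (Ramp1) to 2.81 (Ankrd37). Within secretory or columnar cells Muc4 had log2 folds of 1.31 and 1.55, and Muc1 of 0.61 and 1.05.

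Among the lower genes, Apoe stood at 1607 CPM in wild type and 385 CPM in the labelled knockout at GD15, and at 300.0 CPM in the labelled knockout at GD18 (log2 fold -1.70). Within basal cells its log2 folds were -1.50 and -1.34. Krt10 stood at 410 against 90.5 CPM and at 405 against 120 CPM. Rnaset2a, Ly6k, Cbs, Apoc1, Pdzrn4, Wdr74, Pgf, Eif3j1 and Timp3 were also lower. Serpina1e was almost without tags in the labelled knockout (0.0518 and 0.102 CPM against 108 and 70.4 CPM). Its relatives Serpina1c and Serpina1a were higher there, so the tags of this family are uncertain, as are those of Rnaset2a and Eif3j1.

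**Figure D3:**
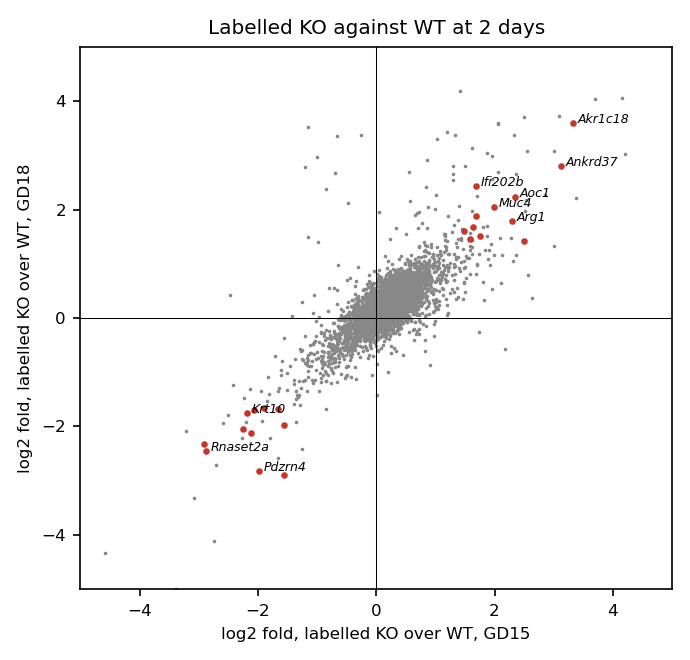
Log2 fold of labelled knockout over wild type epithelium at GD15 (horizontal) and GD18 (vertical); each point is a gene, red points are the genes chosen by rule. Axes end at 5 and -5, which leaves Serpina1e and any other gene past them outside.

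Of the fixed lists, the mucus list had 9 of 16 members higher at GD15 (median 0.67, random lists 0.22) and 7 of 17 at GD18 (median 0.31, random lists 0.23). With TMM scaling 4 members were higher at each day, and with equal weight to the epithelial subclasses 2 and 4. Within secretory or columnar cells the mucus median was 0.01 at GD15 and -0.04 at GD18, under the medians of all genes there of 0.26 and 0.23. Within basal cells it was 1.31 and 0.81, but this rise is not separable from free RNA of secretory cells. The free RNA share was estimated at 22.0% in both labelled knockout libraries against 2.19% and 8.96% in wild type. That estimate divides marker levels in epithelial cells by those in all kept cells. It can therefore also rise where few fibroblast and immune cells were kept, and does not show that these libraries held more free RNA. The glycolysis and hypoxia list had 9 of 20 members higher at GD15 (median 0.54, random lists 0.22) and 7 of 20 at GD18 (median 0.41). With TMM scaling these were 7 and 5, and 1 member was lower at each day under both. Bnip3, Egln3, P4ha1 and Ndrg1 were higher at both days, and Gapdh was lower. The hyaluronan metabolism list was near random lists, at the 17.7th percentile at GD15 and the 26.2nd at GD18. The basal list had a median of -0.30 at GD15, with no member past the fold minimum, and 0.08 at GD18. With TMM scaling the medians were -0.52 (5 of 13 members lower) and -0.21 (2 lower). With CPM the GD15 median was positive with at least 1000 genes per cell (0.29) and with equal weight to the subclasses (0.19). At 1000 genes a Krt5-rich cluster of 3141 cells, with Nrtn and Apoe among its leading genes, was left unnamed. Of its cells 18.7% were wild type GD15 and 1.27% labelled knockout GD15, so that positive median cannot be put down to the filter alone.

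The last comparison asked whether the step from GD15 to GD18 differed between genotypes. Cholesterol synthesis genes were lower at GD18 than at GD15 in the labelled knockout and nearly level in wild type. Prap1, Guca2b, Sult1d1, Napsa and Klk1 gave the largest differences. Those of Prap1 and Sult1d1 were smaller without cluster 32 and that of Napsa reversed. Guca2b had 1 UMI and Klk1 no UMI in wild type at GD18, so a floor of 3 counts sets the size of their differences. None of these differences was tested, since each rests on 4 single libraries.

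In the labelled knockout 11 of 20 cholesterol synthesis genes were lower at GD18 than at GD15, with a median log2 fold of -0.64. In wild type 1 of 20 was lower, with a median of 0.00. Against wild type, the list stood higher at GD15 (median 0.45, 7 of 20 members higher) and lower at GD18 (median -0.20, 3 of 20 members lower). With TMM scaling 3 members were higher at GD15 and 7 lower at GD18 (median -0.48). With equal weight to the subclasses 1 was higher at GD15. Insig1 had a log2 fold of -1.35 between the labelled knockout days. The log2 fold of Rbp2 was lower at GD18 by -2.01 (interval -2.10 to -1.92). Ifitm1, Timp3 and Ulk4 also had lower folds at GD18. Prap1, Guca2b, Sult1d1, Napsa and Klk1 had higher folds at GD18. Without cluster 32 the differences were 2.65 for Prap1, 3.04 for Sult1d1, -1.28 for Napsa and, resting on that floor, -2.06 for Guca2b. Cluster 32 held 0.842% and 0.0418% of labelled knockout epithelial cells at GD15 and GD18.

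Outside the epithelium, classes with at least 100 cells in both libraries were endothelial cells at GD6 and GD12, neutrophil-like cells in the non-pregnant, GD6 and GD12 libraries, and macrophage-like cells in these and in labor. Immune cells differed between the non-pregnant cervix and pregnancy. Squamous and mucus genes also differed in them as in the epithelium, which is what free RNA in the droplets gives, and are left out.

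In neutrophil-like cells, Siglecf stood at 14.6 CPM in the non-pregnant library, 194 CPM at GD6 and 114 CPM at GD12, and Ltc4s at 9.76, 191 and 147 CPM. The marker lists held no eosinophil class, so another mix of granulocytes inside this class cannot be told apart from a change in neutrophils. Camp was high at GD6 alone (259 CPM) and Ngp stood at 179 CPM at GD6 without a UMI at GD12. In macrophage-like cells, Retnla had no UMI in the non-pregnant library and stood at 751 CPM at GD6, 52.7 CPM at GD12 and 810 CPM in labor. Ccl8 and Cxcl9 were higher at GD6 than in the non-pregnant library. Igkc, Igha and Jchain were lower in the pregnant macrophage-like cells, and these are plasma cell transcripts. In endothelial cells, 17 of 20 interferon genes were lower at GD12 than at GD6 (median -1.09), and Cyp26b1 stood at 137 CPM at GD6 against 0.810 CPM at GD12.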

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

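Tests chosen only after the result was seen were the in-labor label, added squamous tissue, the other cell classes at GD6, the genes inside the window, the cells of no named subclass, the most immune free RNA that markers allow, and leaving out cluster 32. The patterns weighed were also picked after the values had been seen.

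The fold of labelled knockout over wild type epithelium had opposite signs at GD15 and GD18 for 2 lists and 6 genes by the rule used here. A list counted where its median lay outside the central 95% of random lists at both days, on opposite sides, and other lists whose medians changed sign did not. Genes were looked for only among those with the largest differences between days, and counted where the intervals excluded no change at both. None of these differences was tested, since each group is 1 library. The epithelial cytokine list had medians of -0.16 and 0.53, a difference of 0.69, but its GD15 median was positive without cluster 32 (0.15) and with no expression minimum (0.26). The cholesterol synthesis list had medians of 0.45 and -0.20, a difference of -0.65. Rbp2 had log2 folds of 1.74 and -0.27, a difference of -2.01, and Ifitm1 of 0.82 and -0.61, a difference of -1.42. Prap1, Sult1d1, Napsa and Klk1 were lower at GD15 and higher at GD18, with differences of 4.69, 4.02, 4.00 and 3.98. Prap1, Napsa and Klk1 lead cluster 32. Without it the difference of Napsa was -1.28, so the share of this cluster may carry it. Prap1 kept 2.65 and Sult1d1 3.04. Leaving out the cells does not take off their free RNA in other droplets, so this cannot show whether the cluster carries those differences too. Klk1 had no UMI in wild type at GD18, so its difference rests on a floor of 3 counts and could not be given without the cluster.

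The 24 genes that set the labelled knockout epithelium apart at both days kept a median of 88.1% of their log2 fold inside the subclass in which they are highest (quartiles 74.1% and 104%). At GD15 the part kept ran from 41.6% for Muc1 to 132.7% for Timp3, with 65.9% for Muc4, 67.0% for Akr1c18 and 68.4% for Arg1. Inside the cells of no named subclass, where no gene was highest, the 24 genes kept 97.3%. This argues against another mix of the named subclasses as the whole source and leaves it open as a part. A subclass can hold several clusters, and the genotypes lay largely in different ones. Clusters 18, 20, 21, 25 and 26 held 76.0% and 76.6% of labelled knockout epithelial cells against 14.2% and 24.7% in wild type. Another mix of cell states inside a subclass therefore stays open. The 24 genes kept 99.3% with cells thinned to the same depth, which argues against the greater weight of cells with many UMIs. Random thinning keeps each cell's expected mix of genes, so effects of depth on filtering and naming were not tested. Strain segments within 20 Mb of Has1, Has2, Has3 and Pgr could not hold most of them, as 16.7% lie there (interval 4.74% to 37.4%, against 6.89% of all genes). Longer segments, and effects of a segment on genes elsewhere, were not tested. The genes inside the window number 4 (Ndrg1 and Ly6k near Has2, Rnaset2a and Cbs near Has1, where the share of all genes would give 1.65), and for these a linked strain segment and the deletion cannot be told apart. Loss of hyaluronan, another strain background and any other difference between the animals or library batches stay open and untested. The free RNA share was estimated at 22.0% in both labelled knockout libraries against 2.19% and 8.96% in wild type. Its subtraction reversed 0 of 118 values of named genes in all comparisons and moved 1 by more than 1.5-fold. At GD6, however, that subtraction left 53.3% of the macrophage gene Lyz2 in the epithelial sums, so free RNA stays open too.

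Krt16 stood near the non-pregnant level in labor and most cornification genes stood above GD18, though 12 of 20 were lower than in the non-pregnant library. A non-pregnant library like the one here under that label is argued against by 12 genes that are high from GD6 to GD18. Their median log2 fold in labor over non-pregnant was 1.47 (7 of 12 at 1 or more, Aqp8 4.37, Adh1 near 0). They were chosen by folds over this same non-pregnant library, so genes low in it alone would also read higher in labor. Another non-pregnant library with more of their transcripts is therefore not excluded. The non-pregnant library drew on 7 diestrus and 2 estrus animals, so one with other cycle stages is not covered. Squamous cells added to an epithelium like that of late pregnancy would leave its clusters in place, but these held 0.959% of in-labor epithelial cells (24 of 2502). A dissociation response stays open: in the 1011 cells without Fos, Fosb or Atf3 UMIs a median of 79.6% of the level was kept, just under the 80% set beforehand, from 12.0% for Sprr2d to 97.6% for Krt14. A dissection made up wholly of other squamous tissue and a change of the cervix with labor also stay open and untested.

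Interferon and antigen presentation lists were higher in GD6 epithelium. Against GD12 the interferon median kept 102.3% with cells thinned, which argues against the greater weight of cells with many UMIs as the whole source. Thinning keeps each cell's expected mix of genes, so effects of depth on filtering and naming were not tested. Subtraction of free RNA kept 100.3% of the interferon median, and 103.4% for the class II genes H2-Aa, H2-Ab1, H2-Eb1 and Cd74, past the bounds set beforehand. Those bounds were wrong, since the subtraction left 53.3% of Lyz2 and 72.3% of C1qa, macrophage genes, in the epithelial sums. With the most that 8 immune marker genes allow (2.26% of the summed immune levels) taken off at GD6 alone, the interferon median kept 70.8% (1.29 against 1.82), between the bounds of 50% and 80%, and no class II gene stayed higher, so immune RNA cannot be told apart from the epithelium's own expression for class II genes and stays open for a part of the interferon difference. In other classes the list was higher at GD6 in endothelial (median 1.09) and macrophage-like cells (0.51) and not in neutrophil-like cells (-0.11, at the 2.69th percentile of random lists), so a response of the whole tissue stays open. A response to early pregnancy, infection or another difference between these animals was not tested.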

How the results depend on the processing

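The alternatives chosen only after the data had been seen were removal of the highest doublet scores at an expected rate, counting unnamed Krt5-rich clusters as epithelial, and leaving out cluster 32. Which shares and list counts to follow in full was also chosen after values had been seen, and the cholesterol count between the labelled knockout days was added last. With 1 library per group, no library could be left out and no other split of the libraries could be drawn. No paired analysis was possible because no animal or library is matched to another. A list median was called where it lay outside the central 95% of random lists.

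Of 1371 values of named genes under the alternatives 3 reversed, and of 4612 list medians 41 reversed. A further 415 and 1813 left their intervals for counting error without reversing. Values of named genes moved by more than 1.5-fold for 31 of 118 with cells thinned (by up to 3.53 in log2), 28 of 74 with equal weight to the subclasses, 24 of 117 without cluster 32 (up to 7.38), 14 of 118 with the mean of per-cell CPM, 8 with the highest doublet scores removed and 7 at 1000 genes per cell, and for at most 1 under each other setting. At GD6 against non-pregnant, between 16 and 28 cornification genes were lower, between 14 and 19 mucus genes higher and between 15 and 20 interferon genes higher under each of 14 alternatives. GD6 had a lower epithelial share than the non-pregnant library under each of 7 alternatives. Of the class shares 111 values left their counting interval and 281 did not. The cause was not tested for any change below, except where it is given. At 1000 genes per cell, clusters of 3141 and 1296 cells with Krt5 in 100% of cells were left unnamed by the rule. The larger held 37.6% GD12, 18.7% GD15 and 38.1% GD18 wild type cells, and 1.27% and 0.923% labelled knockout cells. With the highest doublet scores removed, such a cluster of 1713 cells, 58.8% non-pregnant and 41.2% in labor, was left unnamed. All epithelial values at both settings carry this naming as well as the filter.

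Epithelial shares at 200 genes per cell were 63.6% for non-pregnant, 70.1% for GD12, 78.9% for GD15, 91.2% for GD18, 63.8% in labor, and 90.3% and 93.6% for the labelled knockout at GD15 and GD18. At 1000 genes and 10% mitochondrial counts they were 71.9% for non-pregnant, 65.8% for GD6, 56.7% for GD12, 57.7% for GD15, 71.3% for GD18, and 98.9% and 99.0% for the labelled knockout, and the neutrophil-like share at GD6 was 4.23%. With doublets kept they were 50.4% for GD6, 65.0% for GD12, 75.8% for GD15, 89.8% for GD18, and 87.9% and 89.0% for the labelled knockout. With the highest doublet scores removed they were 58.4% for non-pregnant, 52.5% for GD6, 68.3% for GD12, 85.2% for GD15, 95.5% for GD18, 50.04% in labor, and 96.2% and 95.6% for the labelled knockout. At Leiden resolution 0.5 they were 62.8% for GD12, 80.4% for GD15, 92.0% for GD18, and 89.7% and 91.4% for the labelled knockout. At resolution 2 they were 86.7% for non-pregnant, 51.2% for GD6, 62.6% for GD12, 80.4% for GD18, 87.3% in labor, and 88.9% and 90.5% for the labelled knockout. With unnamed Krt5-rich clusters counted they were 89.98% for non-pregnant, 55.0% for GD6, 78.8% for GD12, 93.0% for GD15, 98.1% for GD18, 93.2% in labor, and 98.9% and 99.0% for the labelled knockout. This last setting can only raise them.

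The 9 mucus genes higher in the labelled knockout at GD15 became 5 at 1000 genes per cell, 4 with TMM scaling, 2 with equal weight to the subclasses and 2 at a fold of at least 2. The 7 at GD18 became 4 under the last 3 of these. The 7 cholesterol genes higher at GD15 became 2 at 1000 genes per cell, 4 without the 50 most abundant genes, 3 with TMM scaling, 1 with equal weight and 0 at a fold of at least 2. The 11 cholesterol genes lower at GD18 than at GD15 in the labelled knockout became 1 at a fold of at least 2, a stricter call by construction. The 15 cornification genes higher in labor than at GD18 became 27 with no minimum, which lets more members in.

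Reversed list medians at 1000 genes per cell were antimicrobial at GD12 against GD6 (0.11), and basal (0.29) and cell cycle (-0.086) in the labelled knockout at GD15. At 200 genes the blood list reversed there (-0.38). With cells thinned, blood at GD15 against non-pregnant (-0.29), tight junction at GD15 against GD12 (-0.035) and cornification in the labelled knockout at GD18 (0.14) reversed. With the mean of per-cell CPM, blood at GD15 against non-pregnant (-0.87), tight junction at GD18 against non-pregnant (-0.040) and tight junction at GD15 against GD12 (-0.014) reversed. With free RNA subtracted, interferon between the labelled knockout days reversed (-0.023).

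With equal weight to the subclasses, Has2 in the labelled knockout at GD15 reversed (-0.011). So did endoplasmic reticulum stress (0.088) and collagen (0.19) at GD15 against non-pregnant, mucus at GD18 against GD15 (-0.044), basal in the labelled knockout at GD15 (0.19), and interferon (-0.0056) and glutathione (-0.014) between the labelled knockout days. This setting gave no value for GD6 and GD12, which had 0 and 14 suprabasal cells.

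With members measured at a CPM of 20, collagen at GD12 against non-pregnant (0.028), cytokines at GD12 against GD6 (0.079), tight junction at GD15 against GD12 (-0.021) and NF-kB in labor against GD18 (-0.054) reversed, with cornification (0.60) and prostaglandin (0.042) in the labelled knockout at GD18. With no minimum, antimicrobial (-0.078) and collagen (0.78) at GD12, collagen at GD15 (0.15), antigen presentation at GD18 (-0.16) and collagen in labor (0.46) reversed against non-pregnant. So did hyaluronan in labor against GD18 (-0.019), cytokines in the labelled knockout at GD15 (0.26) and cornification there at GD18 (0.34).

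With the highest doublet scores removed, basal (0.097), antimicrobial (-0.33) and collagen (0.091) at GD12 and basal at GD15 (0.091) reversed against non-pregnant, and basal (-0.088) and collagen (-0.13) in labor against GD15. With unnamed Krt5-rich clusters counted, blood in labor against non-pregnant (0.77), and antimicrobial (0.10) and blood (-0.37) at GD12 against GD6 reversed. Without cluster 32, the difference between days of Napsa (-1.28) reversed, and so did cytokines in the labelled knockout at GD15 (0.15). The cluster may carry the difference of Napsa, which had only 5 UMIs in wild type epithelium at GD18. That of Guca2b (-2.06) reversed too, but it had 1 UMI in wild type at GD18, so a floor of 3 counts sets its value and the reversal is uncertain.

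Depth limits Has1, with 3 UMIs and 1 UMI in wild type epithelium at GD15 and GD18. The free RNA shares subtracted ran from 1.40% in labor to 23.5% in the non-pregnant library, were 2.19% and 8.96% in wild type at GD15 and GD18 against 22.0% in both labelled knockout libraries, and rest on 14 to 36 marker genes, which makes them uncertain where few immune cells were kept.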

Other observations

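Of the fixed lists not described above, some lay outside the central 95% of random lists at GD6 against non-pregnant. Non-cornified squamous genes had a median log2 fold of -1.52, basal genes of -0.89, cholesterol synthesis genes of -0.67, cell cycle genes of -0.17 and blood genes of -1.44. Antimicrobial genes had a median of 1.54, water and ion transport genes of 1.53, matrix proteases of 1.26 and steroid response genes of 1.02. The cytokine, NF-kB, kallikrein, endoplasmic reticulum stress, prostaglandin, glutathione, collagen, hyaluronan and dissociation stress lists lay within that range.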
